A study of Caenorhabditis elegans with 2 samples.

How the data were processed

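Chromatin immunoprecipitation against eGFP-tagged DAF-12 was sequenced from whole L4 larvae of a C. elegans strain that carries the tagged transgene, in 2 biological replicates of 1 group, per the labels. Each replicate has a list of regions called on that replicate alone, and the series has a list of regions called on both together and a list thresholded for reproducibility between replicates (IDR). Per the labels' text lists, the replicate and pooled lists derive from the ChIP alignments and a control file, and the thresholded list derives from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. All lists were deposited on ce10 and on ce11. The ce11 lists were used for every position, and the ce10 lists only for counts and overlaps.

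The deposited signal of each region is the enrichment value in the narrowPeak signal column, with a scale that is not stated, so it was used only to rank and describe regions within its own list. The deposited −log10 q-values reached 2.08 for all 48 thresholded peaks and for 61 regions of the pooled list, so ties at this value do not rank them. At a q-value below 0.05 the pooled list holds 1709 regions, so most of its 30000 regions do not pass that value. The pooled and replicate 1 lists end at exactly 30000 regions. Read counts and depth per sample are unknown, so no counting interval is given.

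Positions were annotated with the Ensembl release 115 annotation of the WBcel235 assembly, which has the ce11 coordinates, and 0 regions of the ce11 lists ran past a chromosome end. Mitochondrial coding genes and let-7 took their symbols from the RefSeq table of the same assembly. Starts are transcript starts, coordinates are 1-based, and distances run from the summit. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and blastn 2.17.0.

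The tests, the gene lists, the motifs and the rule for named genes were fixed before the data were examined. Named genes were those nearest to the 25 peaks of largest signal, every gene of the 16 lists with a start within 2 kb of a peak, up to 5 per list, and daf-12, unc-119, daf-9, let-7, mir-48, mir-84, mir-241, lin-28, hbl-1 and fard-1 in any case. Promoter shares used a two-sided Fisher's exact test against the other pooled regions. Gene classes used a two-sided Fisher's exact test over genes with a start within 2 kb of a summit, against genes near any pooled region, with Benjamini-Hochberg adjustment over classes and biotypes with at least 3 background genes. Motifs were searched on both strands within 100 bp of the summit in 7 forms, against 5 control regions per peak matched on promoter status and on GC content in bins of 10 percentage points. Chromosome spread used 10000 draws from the pooled regions, and replicate overlap used 10000 permutations of the ranks of replicate 2, with at least 1 bp of overlap. These p-values treat regions or genes as units, and neighbouring ones are not independent.

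Each test was tested on simulated data, 40 lists with nothing planted and 40 with a planted excess, for 48 and for 21 peaks drawn from the nuclear regions. Planted excesses were called in 100% of lists. For the promoter, motif and chromosome tests they were larger than the excess observed at the nuclear peaks. Power at the observed sizes was therefore not tested. With nothing planted, the promoter, motif, chromosome and overlap tests called at most 7.5% of lists, but the gene class test called 35% at 48 peaks and 42.5% at 21 peaks. A test with regions as the unit, which called 0 lists, was therefore added after seeing the data. The analyses of nuclear peaks alone and of protein-coding starts alone were also added after seeing the data. Other alternatives changed the list (its upper 50% by signal, or as many top regions of 1 replicate), the promoter limits, the gene distance, the background, the motif window and the overlap that counts as shared.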

Results

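Binding of DAF-12, the nuclear steroid hormone receptor that couples dauer and developmental timing decisions to hormone state, was profiled by ChIP-seq in whole C. elegans larvae at the fourth larval stage. The worms carried an eGFP-tagged daf-12 transgene in an unc-119 mutant background, and both sexes were pooled. There were 2 biological replicates in 1 group. The lists therefore describe regions enriched after immunoprecipitation of tagged DAF-12 at this stage and hold no contrast with another condition. On the ce11 assembly the pooled list held 30000 regions, the replicate 1 list 30000 and the replicate 2 list 23934. The list thresholded for reproducibility held 48 peaks on ce11 and 46 on ce10. Read depth is unknown, because the lists give a signal per region and no counts, and the control libraries were not analysed here. A region's signal is the authors' own value and carries no replicate error.

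The strongest peaks lay on the mitochondrial genome. Of the 48 thresholded peaks, 27 were mitochondrial (56.2%) and 21 were nuclear, and the 24 peaks with the largest signal were all mitochondrial. The mitochondrial peaks had signals of 26.8 to 385.4 with a median of 150.0, and the nuclear peaks had signals of 19.8 to 53.1 with a median of 22.2, against a median of 5.74 over all pooled regions. The summits fell in 11 of the 12 mitochondrial protein-coding genes. The strongest peak, at positions 12391 to 12694 of the mitochondrial genome, had a signal of 385.4 in the coding exon of ND5, a subunit of respiratory complex I. The next lay in ATP6 (2795 to 3098, signal 340.2), a subunit of the ATP synthase, in CYTB (4617 to 4860, signal 299.7) and at the start of COX2 (9533 to 9836, signal 241.5). COX3 held a peak of signal 230.0 and ND6 one of 185.3, and COX1 and ND5 held 4 summits each. ND4L had no summit. The 48 peaks were the first 48 regions of the pooled list by signal, with the same coordinates and the same values.

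**Figure D1:**
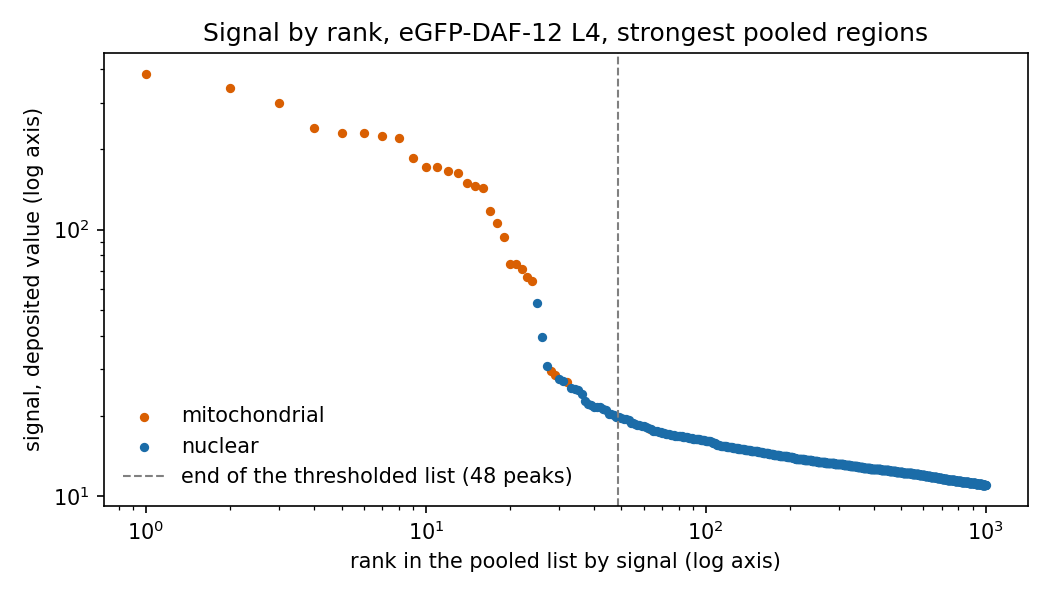
Signal of the strongest 1000 regions of the pooled list against their rank, both on log axes, with mitochondrial regions in orange and nuclear regions in blue. The first 24 regions are mitochondrial with signals from 385.4 down to 63.97, and the thresholded list ends at rank 48 with no step in signal.

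Among the nuclear peaks, 3 lay upstream of mir-241, a let-7 family microRNA of the heterochronic pathway. These nuclear peaks were described after their values were seen, since the rule for named peaks took 24 mitochondrial peaks and 1 nuclear one. The strongest of the 3 (chromosome V, 14366546 to 14366849, signal 39.5) had its summit 415 bp upstream of mir-241 and 2189 bp upstream of mir-48, inside an exon of the noncoding RNA gene F56A12.8. Its region ranked 27 in replicate 1 and 28 in replicate 2. The other peaks of the locus had signals of 25.05 (14368114 to 14368417) and 21.98 (14368712 to 14369015), both intergenic, and lay 1983 and 2581 bp upstream of mir-241. The first of these ranked 32 in replicate 1 and 1105 in replicate 2, and the second ranked 36 and 43.

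**Figure D2:**
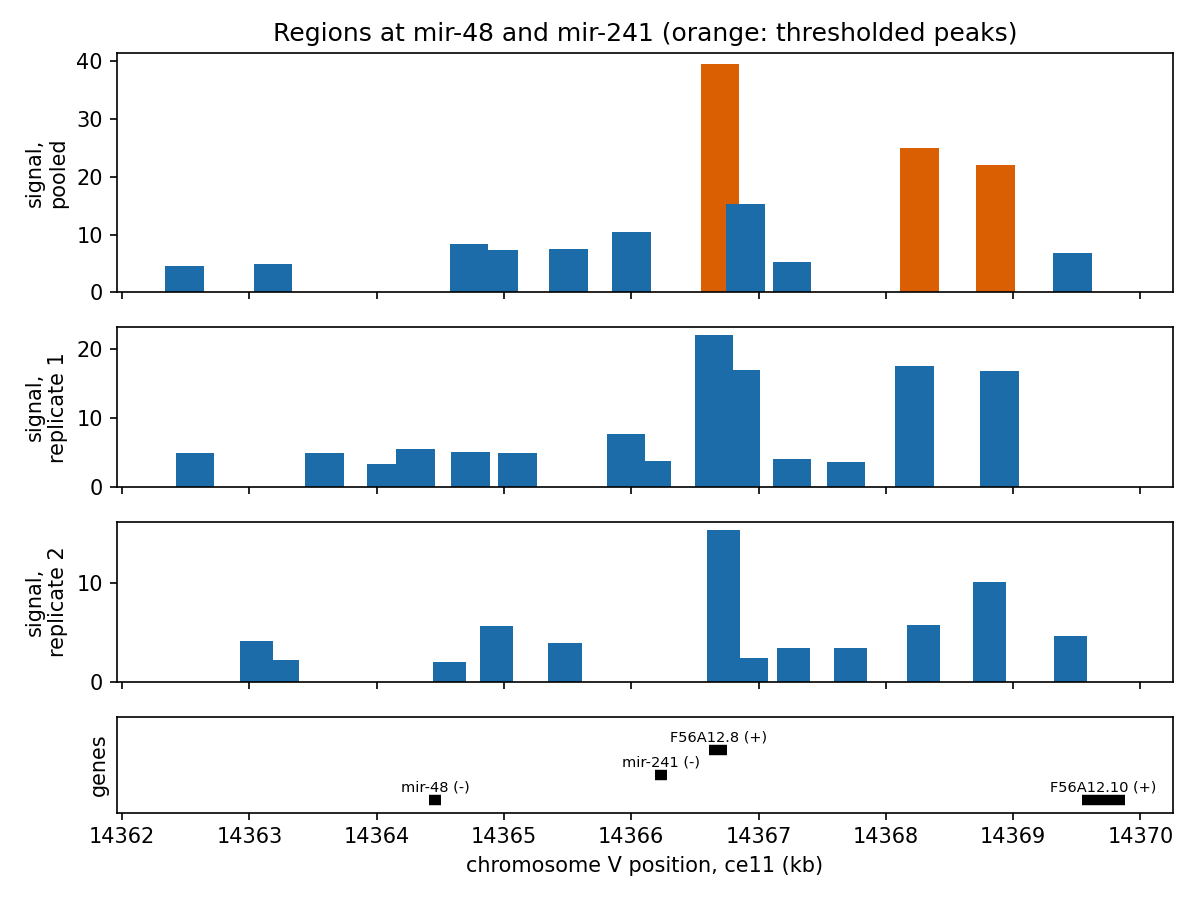
Regions of the pooled list and of each replicate around mir-48 and mir-241 on chromosome V (ce11 position in kb), drawn at their true width with the deposited signal as height, above the annotated genes. Orange bars are the 3 thresholded peaks, with signals of 39.5, 25.05 and 21.98, and blue bars are regions outside the thresholded list.

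The strongest nuclear peak (chromosome III, 12841411 to 12841714, signal 53.1) was intergenic, with its summit 2600 bp upstream of the nearest annotated start, that of Y37D8A.4. It ranked 25 in both replicates. A peak on chromosome II (11619191 to 11619494, signal 22.7) lay in the 5' UTR of din-1, which encodes a cofactor of DAF-12, 735 bp downstream of the nearest din-1 start. That window held 2 copies of AGTGCA spaced as a direct repeat with a 5 bp spacer, AGTGCAACCAAAGTGCA at 11619361 to 11619377. The region ranked 40 in replicate 1 and 565 in replicate 2. Other peaks lay 183 bp upstream of cdc-48.1 (signal 27.1), 90 bp upstream of mgl-1 (20.1), which encodes a metabotropic glutamate receptor, and 269 bp upstream of wwp-1 (22.2), a ubiquitin ligase gene. In that order they ranked 41, 224 and 734 in replicate 1 and 94, 1778 and 36 in replicate 2. The summit near wwp-1 lay in an exon of the noncoding RNA gene Y65B4BR.10. A peak on chromosome II covered the spliced leader gene sls-2.1 (signal 30.8), and one on chromosome IV lay between let-70 and klc-1 (21.5). On chromosome V a peak of signal 21.2 lay 1159 bp from the start of srh-76 and 1456 bp from that of the collagen gene col-140. Within the gene bodies, peaks lay in introns of mom-1 (25.2) and Y41G9A.17 (27.4). Of the 21 nuclear summits, 14 were intergenic and none fell in a coding exon.

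The tagged gene itself had many regions and no thresholded peak. Within 2 kb of the daf-12 gene (chromosome X, 10635908 to 10666875) the pooled list held 33 regions, with 25 in replicate 1 and 31 in replicate 2. The strongest pooled region at daf-12 had a signal of 19.4 and ranked 52, just below the end of the thresholded list. No thresholded peak lay within 2 kb of unc-119, daf-9, let-7, mir-84, mir-48, lin-28, hbl-1 or fard-1. The best pooled rank was 841 at let-7 (signal 11.3), 1368 at mir-48 (10.4), 1637 at fard-1 (10.05), 1855 at daf-9 (9.81), 3344 at unc-119 (8.70), 3829 at lin-28 (8.48), 6654 at hbl-1 (7.42) and 23525 at mir-84 (4.72).

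**Figure D3:**
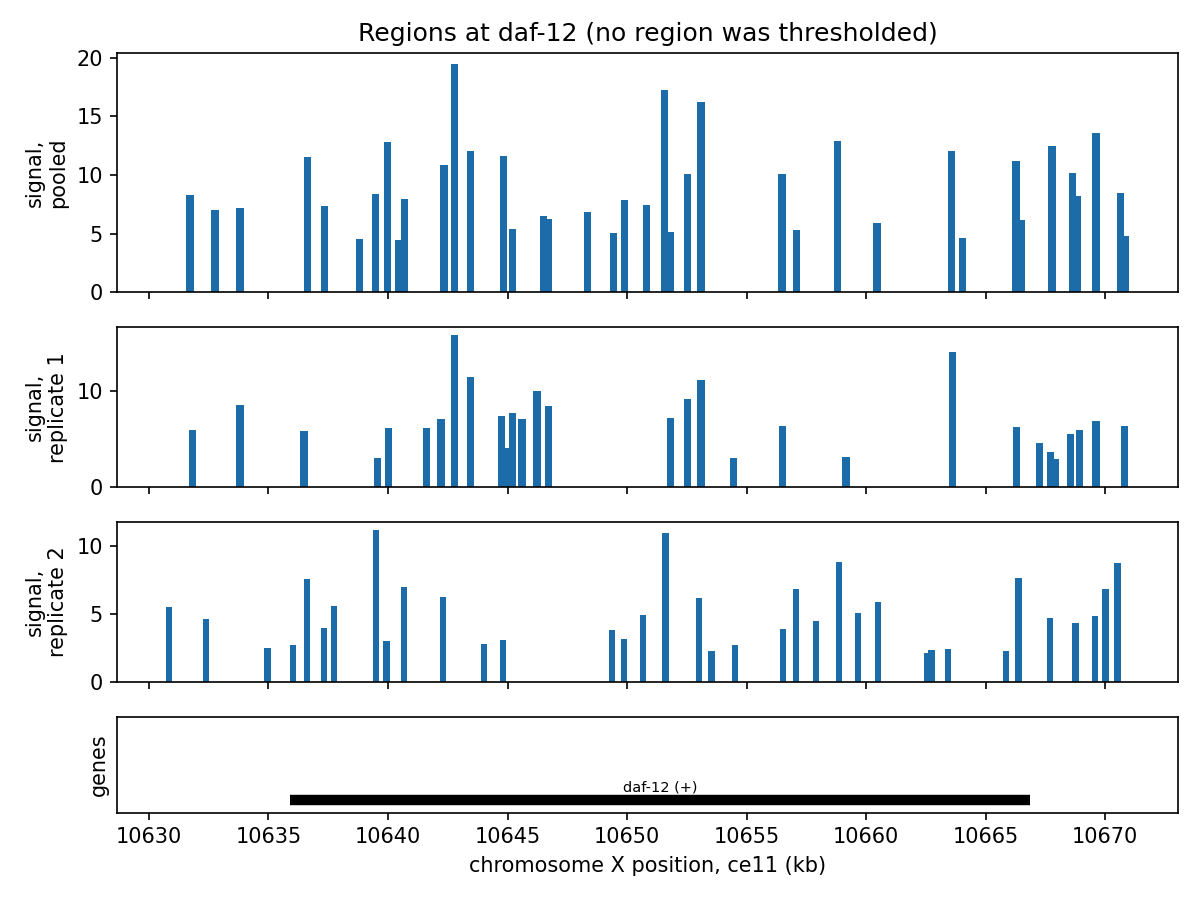
Regions of the pooled list and of each replicate across daf-12 on chromosome X (ce11 position in kb), with the deposited signal as bar height, above the extent of the gene. The strongest pooled region had a signal of 19.4, and none of the 33 pooled regions within 2 kb of the gene was thresholded.

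The strongest regions recurred between the replicates, and most of those that did were mitochondrial. Of the top 48 regions of replicate 2, 27 overlapped a top 48 region of replicate 1, where permuted ranks gave a mean of 0.0742 (one-sided permutation test, p = 0.0001, the smallest that 10000 permutations can give). Among nuclear regions alone, an analysis chosen after the mitochondrial peaks were seen, as were all those of nuclear peaks, 3 of the top 21 were shared against a permuted mean of 0.0099 (one-sided permutation test, p = 0.0001, again the smallest possible). The shared regions were the chromosome III peak (signal 53.1) and the mir-241 peaks of signal 39.5 and 21.98. Both mir-241 peaks belong to 1 locus and are not independent, which the permuted ranks do not allow for. Of the 21 nuclear thresholded peaks, 7 ranked within the first 100 regions in both replicates, 4 in replicate 1 alone, 9 in replicate 2 alone and 1 in neither. The peak near T27A8.8 on chromosome X ranked 13244 in replicate 1 and 30 in replicate 2. Over the top 1000 regions the shared number was 54 against a permuted mean of 12.81 (31 against 11.78 for nuclear regions). Over the top 5000 it was 328 against 234.3 (308 against 231.4 for nuclear regions). That excess was larger in number but smaller relative to the permuted mean. Regions are not independent replicates, so these tests ask only whether ranks agree between the libraries.

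The peaks were unevenly spread over the chromosomes because of the mitochondrial genome. It held 27 peaks where draws from the pooled regions gave 0.0448, and the chi-square statistic was 16238 (permutation test, p = 0.0001, the smallest possible). The X chromosome held 9 nuclear peaks against an expected 4.10, and chromosome V held 5 against 4.27. In the ce10 list X held 7 thresholded peaks and chromosome V held 5. Over the nuclear chromosomes the spread did not pass the threshold (chi-square 9.56, permutation test, p = 0.0807). It passed with the strongest nuclear regions of replicate 2 alone, where X held 10 against 4.24 (permutation test, p = 0.0125), and not with those of replicate 1 (p = 0.13).

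Summits of the thresholded peaks lay in promoters more often than other pooled regions, from 1 kb upstream to 200 bp downstream of a start. The share was 77.1% (37 of 48) against 43.2% of 29947 other regions (Fisher's exact test, two-sided, odds ratio 4.42, p = 2.71e-06). The mitochondrial genes lie close together, and random positions on the same chromosomes gave 68.0% (Fisher's exact test, p = 0.214). For the 21 nuclear peaks the share was 57.1% against 43.2% (Fisher's exact test, odds ratio 1.75, p = 0.27).

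By gene class, genes for tRNA, rRNA and snoRNA were more frequent near the peaks. Of 74 genes with a start within 2 kb of a summit, 26 were tRNA genes against 1.04 expected (Fisher's exact test, adjusted p = 3.34e-28). Most of these 26 were mitochondrial. A further 2, both mitochondrial, were rRNA genes against 0.0143 expected (Fisher's exact test, adjusted p = 0.000744). The 27 mitochondrial peaks were spread over a genome of 13794 bp. Each of its tRNA and rRNA genes had a start within 2 kb of a summit. The rRNA call and most of the tRNA count therefore restate where the peaks lay and are no separate result on gene class. There were 4 snoRNA genes against 0.557 (Fisher's exact test, adjusted p = 0.0156), namely C06A1.9, F07A11.15, M7.15 and T27A8.8. piRNA genes were less frequent, with 1 against 26.4 expected (Fisher's exact test, adjusted p = 4.29e-12), but with regions as the unit that call was lost (Fisher's exact test, adjusted p = 0.34). On simulated lists of 48 nuclear regions with no class planted, the test by genes called at least 1 class in 35% of lists. The test by regions called a class in none of 40. These rates do not cover lists with mitochondrial peaks. Near the 21 nuclear peaks, snoRNA genes held with regions as the unit, at 4 peaks, or 19.05% against 1.57% (Fisher's exact test, adjusted p = 0.00403), and tRNA genes did not (Fisher's exact test, adjusted p = 0.0722). By genes, the snoRNA call was lost when the strongest regions of either replicate alone took the place of the thresholded list (Fisher's exact test, adjusted p = 0.671 for replicate 2 and 0.152 for replicate 1).

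Of the fixed gene lists, the let-7 family and the heterochronic list each had 1 member near a peak, mir-241. For all 48 peaks neither list passed by genes within 2 kb (Fisher's exact test, adjusted p = 0.0739 and 0.134). Both passed within 5 kb with 2 members each (Fisher's exact test, adjusted p = 0.000881 and 0.00469). The neighbouring mir-48 lies within that distance of the mir-241 peaks, so 1 locus can count as 2 genes. For the nuclear peaks the let-7 family passed by genes within 2 kb (Fisher's exact test, adjusted p = 0.0476) and the heterochronic list did not (0.0812). That let-7 family call was lost in the upper 50% of the nuclear peaks, with replicate 1 alone and within 1 kb (Fisher's exact test, adjusted p = 0.0515, 0.0517 and 0.0502). With regions as the unit both passed at 2 peaks, among all 48 (Fisher's exact test, adjusted p = 0.00302 and 0.0197). Both lists also passed among the nuclear ones (Fisher's exact test, adjusted p = 0.00171 and 0.00505). The 2 peaks belong to the mir-241 locus and are not independent, a case that simulated lists of randomly drawn regions do not cover. The list of dafachronic acid and dauer genes had din-1 alone (Fisher's exact test, adjusted p = 0.134). It passed with the strongest 48 regions of replicate 1 alone, where daf-12 joined din-1 (Fisher's exact test, adjusted p = 0.0035). It had no member with those of replicate 2. Those did include daf-12 regions, at ranks 33 and 34, but with summits more than 2 kb from a daf-12 start. However, daf-12 is the tagged gene, and its regions could come from extra copies of the tagged locus. The cuticle list had col-140 alone. The lists for lipid metabolism, xenobiotic metabolism, nuclear receptors, ribosomal proteins, histones, heat shock, intestine, muscle, seam and hypodermis, neurons and germline had no member near a peak.

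DAF-12 half-site hexamers, AGTGCA and AGGACA, were present at 9 of 48 peaks (18.8%) and at 22 of 240 matched control regions (9.17%), a difference that did not pass (Fisher's exact test, adjusted p = 0.389). The nuclear peaks with a hexamer within 100 bp of the summit were those near Y37D8A.4, mir-241, F45D3.1, din-1 and F02E9.5, which is 5 of 21 (23.8%) against 12.4% of controls (Fisher's exact test, adjusted p = 0.422). The peak at mir-241 held AGTGCA on the minus strand at 14366731 to 14366736, within TCAGGGATGCACTTTTATAAA. Among the strongest 48 regions of replicate 1 alone, the share was 22.9% against 7.08% (Fisher's exact test, adjusted p = 0.0151). Among those of replicate 2 alone it was 18.8% against 12.08% (Fisher's exact test, adjusted p = 0.493), higher in the same direction but not past the threshold, and the replicates were not compared by a test. Within 50 bp of the thresholded summits the share passed, at 14.6% against 4.17% (Fisher's exact test, adjusted p = 0.0421). For the nuclear peaks alone it did not pass there, at 23.8% against 6.67% (Fisher's exact test, adjusted p = 0.101). Controls for all 48 peaks came from pooled regions that are nearly all nuclear, so those comparisons set mostly mitochondrial peaks against nuclear regions.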

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

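The settings for nuclear peaks alone, protein-coding starts and regions as the unit were chosen after seeing the data. Over 185 combinations of result and alternative, 122 kept direction and side of the threshold or, for a count, stayed within 1.5 times. A call was lost in the same direction in 23 and gained in 13, 15 changed direction, some of them losing a call, and 12 moved a count. The thresholded list became 24 peaks in its upper 50% by signal, all mitochondrial, and 21 peaks without the mitochondrial ones. Leaving out a replicate was not possible for the thresholded count, since that list needs both. The promoter share of all peaks, 77.1%, lost its call against random positions (Fisher's exact test, p = 0.214). For nuclear peaks the share fell below its background in the upper 50% (40%) and with protein-coding starts only (28.6%), and ran from 33.3% (without replicate 2, below its background of 42.7%) to 61.9% with 1 replicate left out.

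The number of gene classes called, 4 for all peaks including the largely mitochondrial tRNA and rRNA calls, fell to 1 with the nearest start only. For nuclear peaks, also 4, it fell to 0 in the upper 50%, 2 with starts within 1 kb and 0 with the nearest start only, and was 2 to 3 with 1 replicate left out. Among single classes of all peaks, the upper 50% left 0 members of the dauer, heterochronic, let-7 family and snoRNA classes, and the nearest start only left 0 of the first 3. Without replicate 1 the dauer list also had 0 members, and without replicate 2 it had 2, din-1 and daf-12, and gained a call. For nuclear peaks the same dauer list had 0 without replicate 1, and the dauer, heterochronic and let-7 family lists had 0 with the nearest start only.

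No motif was called for all peaks, but 2 half-site forms were with a window of 50 bp to each side. Neither form was called at that window for nuclear peaks alone (Fisher's exact test, adjusted p = 0.101 for each). With 1 replicate left out, 0 to 4 motifs were called. The 4, without replicate 2, were AGTGCA, AGGACA, either of them, and the 8 bp GA repeat (Fisher's exact test, adjusted p = 0.0478 for the GA repeat). For nuclear peaks AGTGCA (1 motif) was called with a window of 200 bp, and 1 to 2 motifs with 1 replicate left out. Without replicate 2 these were half-site forms, and without replicate 1 it was CACGTG (Fisher's exact test, adjusted p = 0.0286). CACGTG had been fixed beforehand as an unrelated hexamer, so half-site calls near the threshold need the same caution. The chromosome spread of nuclear peaks passed with draws by chromosome length (chi-square 11.2, permutation test, p = 0.0457) and ran from 8.35 to 14.6 with 1 replicate left out, passing only without replicate 1. The cause of these changes was not tested, except that the upper 50% of the full list holds no nuclear peak. No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits could not be stated.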

Other observations

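The tests of mitochondrial copy number, of both daf-12 explanations and of chance and local depth at mir-241 were chosen after the result they measure was seen, and the others after the pattern but before the test was run. Of the 9 nuclear peaks on X, 5 held the 9-mer TCGCGCAGG within 100 bp of the summit, and none of the 12 autosomal nuclear peaks did. They are the peaks at 2996904 to 2997207, 6296510 to 6296813, 8036248 to 8036551, 11094065 to 11094368 and 16681978 to 16682281. The 9-mer was noticed in these sequences, and it is part of a motif known from recruitment sites of the dosage compensation complex on X. It was therefore tested on X regions ranked below the thresholded list. Regions that overlap a thresholded peak were not removed, so some may hold the same copies of the 9-mer. There, 3 of the 100 strongest regions held it and 3 of the 5744 others (Fisher's exact test, odds ratio 59.2, 95% interval 7.79 to 445, p = 9.37e-05), against 0 of the 100 strongest autosomal regions. A candidate explanation is that part of the X signal lies at dosage compensation sites. However, the count rests on 3 regions, which were not checked for overlap with the thresholded peaks. Tagged DAF-12 also cannot be separated here from DNA recovered at such sites in any experiment.

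The mitochondrial peaks may reflect the high copy number of mitochondrial DNA. Pooled regions covered 56.8% of the mitochondrial genome against 9.01% of the nuclear genome. The 27 thresholded peaks alone covered 55.4% of it, so this coverage largely restates the peaks. It cannot decide on copy number, since the lists were called with a control file in which copy number would also be high. Binding directed by DAF-12 half-sites stayed open, since 14.8% of the 27 windows held a half-site against a median of 11.1% in shifted windows (permutation test over 10000 circular shifts, p = 0.356). The control libraries, which would show the copy number directly, were not used here, and no biological explanation was tested beyond the half-sites.

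The regions at daf-12 could come from extra copies of the tagged locus. In a 35 kb window, replicate 1 had 25 regions and replicate 2 had 31, where the median of 2861 nuclear windows was 10 and 8. Replicate 2 exceeded every window (at most 28 regions). However, replicate 1, at percentile 99.86 with a window maximum of 29, fell between the limits set for and against extra copies. These counts therefore cannot tell extra copies from a dense locus. The lists were also called with a control file. If it came from this strain, extra copies would count there too, and no percentile could decide. Binding at an annotated daf-12 promoter also stayed open, since 7 of the 33 pooled regions (21.2%) lay in such a promoter, with 5 in replicate 1 and 7 in replicate 2. Only the lack of any such region in every list was set to count against it, so this share does not decide. The strongest region lay outside, 1616 bp from the nearest start in replicate 1 and, at another position, 3575 bp in replicate 2.

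The 3 peaks at mir-241 lay within 2166 bp. Random draws of 21 nuclear regions held 3 summits within 2.5 kb, a limit set after the cluster was seen, in 0% of 10000 draws, within 35 kb in 0.06% and within 1000 kb in 28.85%, which argues against independent placement by chance. A higher local read depth, from open chromatin or extra copies, may contribute but cannot be told apart from binding. The 35 kb window held 21 pooled regions, the 99.4 percentile of nuclear windows, and 18 without the 3 peaks, the 96.3 percentile. Binding of DAF-12 at this locus stays a hypothesis.

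Half-sites did not mark stronger nuclear regions by a margin these data resolve. They were present in 13.1% of the 1000 strongest and 11.4% of 4998 matched weaker regions (Fisher's exact test, odds ratio 1.17, 95% interval 0.948 to 1.44, p = 0.131). The strongest nuclear peak, on chromosome III, aligned to the mitochondrial genome over at most 26 bp, which argues against a nuclear copy of mitochondrial sequence there.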
